A study of Mus musculus with 4 samples.

How the data were processed

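Primary colon epithelial cells were taken from mice given 2% DSS for 3 days. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from total RNA with an Illumina TruSeq RNA kit. The groups, wild type and intestinal epithelial Ezh2 knockout, and the replicate numbers come from the labels. The labels say that each group was tested in duplicate but not whether the 2 libraries of a group came from separate mice, so p-values measure only the spread between these libraries, which may be technical.

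The authors deposited a table per library with a gene identifier, its transcripts, a length, an expected count and an FPKM value. Per the file headers, the expected counts are estimated counts that need not be whole, and 78.8% to 80.2% of them were exactly whole as deposited, with no tolerance. The deposited FPKM values are counts scaled to transcript length and library total, per the file headers. The deposited lengths (unit other) were not used in the tests of genes and gene lists, only in the closing check for a trend on GC content and length. The submitters' processing notes name Bowtie2 and BWA, with no role or version, and the human build hg19. The organism in the labels is mouse, and the deposited transcripts are RefSeq accessions of which 99.72% of gene identifiers, 18820 of 18872, matched the mouse RefSeq gene table (assembly GRCm38.p6). That table gave the gene symbols. Because the build named in the notes is not a mouse build, no coordinates are given. The quantification tool is not given in the sources used here.

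Genes not listed in a file were taken as 0. The replicate 1 files share an annotation and the replicate 2 files share another. Between numbers, 573 to 577 genes had other transcript lists, against 0 within a number, 165 genes were listed only by both replicate 2 files and 344 only by both replicate 1 files. Ly6g, for example, had 1137 and 1015 counts in the replicate 2 libraries and was not listed in the replicate 1 libraries, so its fold change is not a measurement. Of 13608 tested genes, 538 had transcript lists that differed or were listed by 1 version only, and 195 of the 5953 called genes were among them. None of the called genes was listed by 1 version only. Aebp2, Nos2, Klk1, Mmp7, Dnajb1 and Pmvk are among the named genes whose transcript lists differ. No mitochondrially encoded gene was listed, so that list was not tested.

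Libraries were compared before averaging. The comparison used genes with the same transcripts and whole counts in all 4 libraries and at least 20 counts summed over a pair. Genes that differ between the annotations were thus left out. Chi-square per degree of freedom was 2.18 between the wild-type libraries, 2.95 between the knockout libraries and 38.25 to 44.59 between groups. Libraries of a group therefore differed beyond sampling noise and were kept separate.

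A limma test on log2(FPKM + 1) had been planned for the case that the files held only FPKM, with edgeR in its place if they held counts. Because the files hold expected counts, these were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, 2 libraries against 2, no block, two-sided, adjusted p under 0.05 after Benjamini-Hochberg). TMM factors were 1.036 and 1.035 in wild type and 0.9647 and 0.9663 in knockout. The standard error is the absolute log2 fold change divided by the square root of the F statistic. The common dispersion was 0.0166, a biological coefficient of variation of 12.9%. Where a group had no count in any library, the fold is a lower bound against a floor of 3 counts per library. Where a group had few counts, a ratio of summed counts is given with an exact Clopper-Pearson interval of 95%. Intervals and floors cover counting error only.

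Gene lists were fixed before the data were examined and tested with camera (limma 3.58.1) with a preset correlation of 0.01, and adjusted over the 30 lists with at least 5 measured genes. Each list was also tested with an estimated correlation and with fry. With an estimated correlation camera uses only the few residual degrees of freedom of the 4 libraries, so a list can hardly pass the adjustment. Some genes are in several lists, for example S100a8 among defence and neutrophil genes. The defence and erythroid lists each have 1 member with no counts in a group, and their medians are the same with that member at its bound. Named genes follow a rule fixed before the data were examined: the PRC2 subunits, Traf2, Traf5, Itch, Tnf and Cdh1, the 12 genes with the largest rise and the 12 with the largest fall among called genes with no overlap between groups and a gene name, up to 4 members by p of each list past the threshold, 2 of each other list, and the 2 most abundant members of lists for other cells and RNA handling. Saa1, Saa2, Pigr and Lypd8, and the genes named in the closing section outside this rule, were chosen after their values were seen.

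The tests were run on simulated counts for 13361 genes with the means and library sizes of the knockout and wild-type comparison. Of 50 genes changed at each size, 7 were recovered at 1.5-fold, 39 at 2-fold, 49 at 4-fold and 48 at 8-fold, and 0.137% of unchanged genes were called. A list of 20 genes raised 1.5-fold was called and 0 of 29 unchanged lists were. Simulated genes were drawn independently of each other, whereas estimated correlations within the real lists reached 0.771. The simulation therefore does not test whether camera's preset correlation is adequate. The simulation changed far fewer genes than passed in the real comparison, which makes its adjusted threshold stricter, so these rates of recovered genes do not carry over to it.

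Alternatives were other filters (no filter, mean FPKM of at least 5), scalings (DESeq2 size factors, library totals, quantile normalization, FPKM rescaled to equal totals), DESeq2 1.42.0, limma on log2 FPKM with pseudocounts of 1, 0.1 and 0.01, eBayes without trend or robust, a replicate block, genes with the same transcripts in all files, lists without genes that 1 annotation version lists, thresholds of 0.1 and of a log2 change of 1, and each library left out. Scaling by a median of log ratios was run on the counts, as DESeq2 size factors in edgeR, and not on FPKM. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9 joined the files and drew the plots.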

Results

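RNA was sequenced from primary colon epithelial cells of mice given 2% dextran sulfate sodium (DSS), a polysaccharide that injures the colon lining and induces colitis, for 3 days. Wild-type mice gave 2 libraries. The other 2 libraries came from mice lacking Ezh2, the histone methyltransferase of Polycomb repressive complex PRC2 that silences genes, in the intestinal epithelium (knockout). The estimated counts summed to 5037367 and 5236519 in the wild-type libraries and to 5399949 and 5446998 in the knockout libraries. The design asks how loss of epithelial Ezh2 changes gene expression in the colon epithelium during experimental colitis. Libraries from mice without DSS were not analysed here, so each value below is a difference between genotypes under DSS. Fold changes are on the log2 scale, knockout minus wild type, with their standard error, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. FPKM values are means ± SD with n = 2 libraries per group.

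Ezh2 itself (Entrez gene 14056) was counted at 105 and 102 in the wild-type libraries and at 86 and 83 in the knockout libraries. Its FPKM was 7.54 ± 0.36 in wild type and 5.82 ± 0.18 in knockout, a log2 fold change of -0.27 ± 0.17 that did not pass the threshold (adjusted p = 0.218). On FPKM values rescaled to the same total in each library, limma gave -0.42 with an adjusted p of 0.0469. The labels do not say which part of the gene was removed, and a count over the whole gene does not show whether an exon is missing, so this value neither checks nor contradicts the labels. Of the 11 measured PRC2 subunits, 1 rose and 2 fell, with the same counts when adjusted over the list alone, and the list did not pass camera's test (adjusted p = 0.508). Ezh1, the other methyltransferase of the complex, fell from 21.0 ± 2.13 to 8.62 ± 0.71 FPKM (log2 fold change -1.18 ± 0.12, adjusted p = 6.52e-05). Phf1 fell by 0.55 and Rbbp7 rose by 0.36 on the log2 scale, and Rbbp7 did not pass without wild-type replicate 2 (0.34, adjusted p = 0.0697). The core subunits Eed and Suz12 had log2 fold changes of 0.23 and 0.25 and did not pass, nor did Rbbp4, Jarid2, Aebp2, Mtf2 and Phf19. With a library left out, the log2 fold change of Suz12 ranged from 0.039 to 0.48, the highest without wild-type replicate 1.

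Of 13608 genes tested, 3129 were higher and 2824 lower in the knockout, 43.7% in all. A log2 change of at least 1 was seen for 939 of the higher and 1091 of the lower genes. The split between directions depended on the scaling within each test. In edgeR, higher genes made up 52.6% of the called genes with TMM factors and 42.4% with library totals alone, with a median log2 fold change of all genes of -0.002 and -0.103. With limma on log2(FPKM + 1) they made up 44.1% without rescaling, 36.4% rescaled to equal totals and 49.8% quantile normalized, with medians of -0.079, -0.158 and -0.009. Among the named genes with the largest rises, Reg3b, an antimicrobial lectin, was not counted in wild type and was counted at 73 and 85 in knockout, at least 26.7-fold higher. Cdkn2a, the cell cycle inhibitor locus and a textbook Polycomb target, went from 1 count in each wild-type library to 153 and 165 in the knockout libraries, a ratio of 162 with a 95% exact binomial interval of 44.3 to 1340. Myot, which encodes a muscle Z-disc protein, was at least 17.9-fold higher. The chemokine gene Cxcl3 was at least 6.6-fold higher and Pdx1, a transcription factor of duodenum and pancreas, at least 5.41-fold. Gbp10, Gml2, Ppef1, Dmgdh, Krt90 and Tmem74b also had no counts in wild type and were at least 4.73-fold to 8.13-fold higher. With limma on log2(FPKM + 0.01), Gbp10, Krt90 and Tmem74b did not pass (adjusted p = 0.111, 0.141 and 0.0583). Tgtp1, an interferon-inducible GTPase with a near-identical neighbour Tgtp2, rose from 0.50 ± 0.70 to 58.5 ± 2.63 FPKM.

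Among the named genes with the largest falls, Cyp2c55, a colonic cytochrome P450, fell from 186 ± 16.4 to 0.61 ± 0.33 FPKM (log2 fold change -8.14 ± 0.21, adjusted p = 3.53e-08). Sycn, which encodes a secretory granule protein, fell from 1816 ± 150.2 to 40.9 ± 10.6 FPKM. Cyp2f2 fell from 20.2 ± 0.12 to 0.40 ± 0.28 FPKM. Itih2 was counted at 115 and 112 in wild type and at 2 and 0 in knockout, a ratio of 112 with an interval of 30.6 to 928. Hsd3b2 was 50.2 times higher in wild type, with an interval of 8.62 to 2020. Klk15 was at least 15.7-fold lower, Wnt8b at least 10.6-fold and Cdh26 at least 4.1-fold. With limma on log2(FPKM + 0.01), Wnt8b and Cyp2c69 did not pass (adjusted p = 0.0537 and 0.0516). The alpha-globin copy Hba-a2 was at least 36.9-fold lower. Hba-a2, Cyp2c69, Methig1, Mettl7a2, Gbp10 and Cyp2c55 have close paralogs, so reads could be split between copies and their values are uncertain. The Cyp2c55 counts, 1983 and 1821 in wild type and 9 and 4 in knockout, were whole as rounded and show no such split. Counts of Hsd3b2, Gml2 and Cxcl3 were not all whole, so the same caution holds for them.

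**Figure D1:**
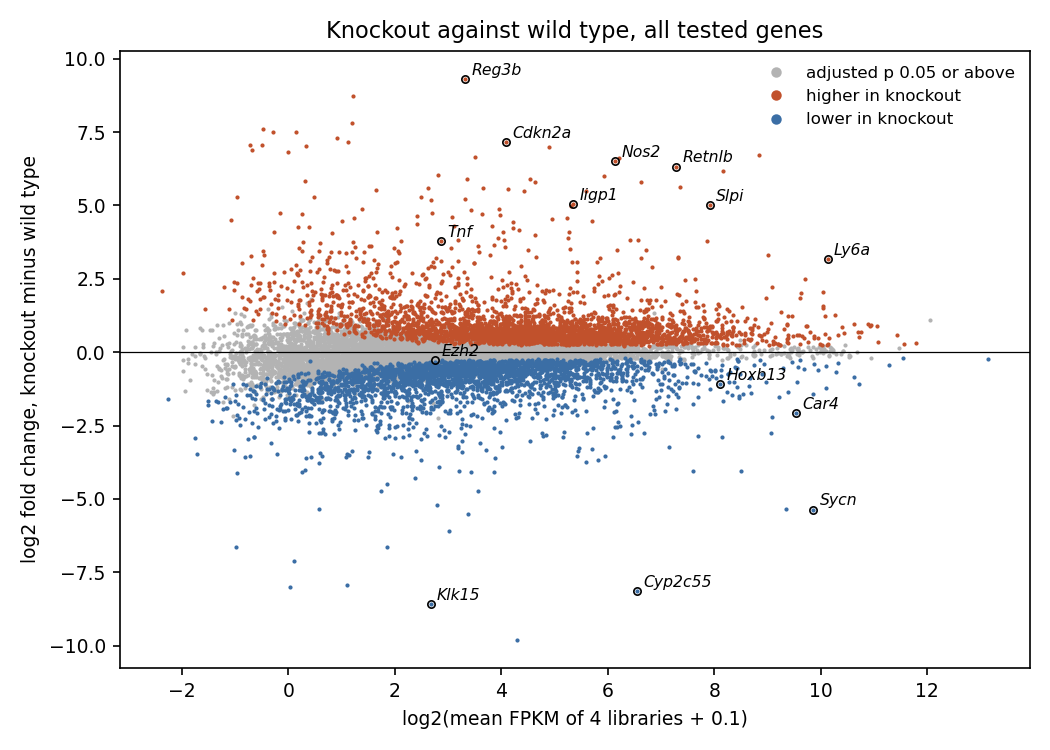
Each point is a tested gene, with the log2 mean FPKM of the 4 libraries on the x axis and the log2 fold change, knockout minus wild type, on the y axis. Genes higher (3129) and lower (2824) in the knockout at the adjusted threshold are coloured, and Ezh2 lies near 0 while Cdkn2a and Cyp2c55 lie near the extremes; for genes with no counts in a group the plotted fold is the fitted one and not a bound.

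Most genes of mucosal and antimicrobial defence rose in the knockout. Of 22 measured, 18 rose and 4 fell, with the same counts when adjusted over the list alone, and the median log2 fold change was 3.79 (camera adjusted p = 2.34e-31, adjusted p = 0.176 with an estimated correlation). Nos2, the inducible nitric oxide synthase, rose from 1.66 ± 0.23 to 139 ± 1.91 FPKM. Retnlb, a goblet cell antibacterial protein, rose from 4.04 ± 1.67 to 306 ± 43.0 FPKM. Slpi, a secreted protease inhibitor, rose from 15.4 ± 2.0 to 466 ± 55.2 FPKM, and Duoxa2, the maturation factor of an epithelial hydrogen peroxide source, from 18.4 ± 1.03 to 191 ± 12.6 FPKM. The 4 members that fell, Saa1, Saa2, Pigr and Lypd8, were abundant, and the summed FPKM of the list went from 15530 in wild type to 14570 in knockout. Neutrophil markers rose too, but S100a8, S100a9 and Ltf, which all rose, are in both lists, so the lists are not separate evidence. Of 16 fixed neutrophil genes 7 were measured, of which 5 rose and 0 fell (median log2 fold change 2.25, camera adjusted p = 3.2e-07, adjusted p = 0.235 with an estimated correlation). Without Ly6g, which only the replicate 2 files list, the median of the other 6 was 3.87 (camera adjusted p = 2.09e-08, adjusted p = 0.235 with an estimated correlation). S100a8, which is also in the defence list, rose from 2.14 ± 0.70 to 93.8 ± 5.98 FPKM.

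TNF, the cytokine whose signalling the study addresses, was higher in knockout. Tnf rose from 1.03 ± 0.40 to 13.3 ± 0.33 FPKM (log2 fold change 3.79 ± 0.28, adjusted p = 1.29e-05). The adaptors Traf2 and Traf5 had log2 fold changes of 0.24 ± 0.14 and 0.30 ± 0.23, and the ubiquitin ligase Itch -0.13 ± 0.12. None of these 3 genes passed (adjusted p = 0.195, 0.323 and 0.414). Of 26 measured TNF receptor signalling components, 9 rose and 2 fell, likewise when adjusted over the list alone (median log2 fold change 0.24, camera adjusted p = 0.00955, adjusted p = 0.309 with an estimated correlation). The camera call was also lost in edgeR with a mean FPKM of at least 5 (adjusted p = 0.0734) and on 6 limma fits of FPKM (adjusted p = 0.0506 to 0.0762). The necroptosis kinase Ripk3 rose from 12.1 ± 0.70 to 103 ± 4.71 FPKM, and the receptors Tnfrsf1b and Tnfrsf1a rose by 2.31 and 0.97 on the log2 scale. Of 27 NF-κB response genes, 19 rose and 1 fell, or 20 and 1 adjusted over the list alone (median 1.44, camera adjusted p = 9.23e-13, adjusted p = 0.279 with an estimated correlation). The chemokine Cxcl5 rose from 2.59 ± 0.59 to 76.1 ± 17.7 FPKM and Cxcl10 from 1.24 ± 0.04 to 29.96 ± 0.54 FPKM.

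Interferon-responsive and antigen presentation genes were higher too. Of 34 interferon response genes, 22 rose and 3 fell, or 27 and 3 adjusted over the list alone (median 0.93, camera adjusted p = 1.12e-21, adjusted p = 0.289 with an estimated correlation). Iigp1, an immunity-related GTPase, rose from 2.6 ± 0.14 to 78.6 ± 3.32 FPKM (log2 fold change 5.04 ± 0.12), and the immunoproteasome subunits Psmb8 and Psmb9 rose by 2.46 and 2.89. Of 8 MHC class II genes, 7 rose and 0 fell on either adjustment, over all genes or adjusted over the list alone (median 1.53, camera adjusted p = 5.15e-09, adjusted p = 0.288 with an estimated correlation). Cd74, the invariant chain, rose from 332 ± 6.87 to 1250.4 ± 62.1 FPKM. T and NK cell markers moved the same way. Of 17 measured, 14 rose and 0 fell, or 15 and 0 adjusted over the list alone (median 1.79, camera adjusted p = 8.15e-07, adjusted p = 0.235 with an estimated correlation). Their levels were low, with Gzmb at 0.35 ± 0.30 and 12.2 ± 2.21 FPKM and Cd8a at 0.78 ± 0.24 and 5.35 ± 0.01 FPKM. Of 19 macrophage and dendritic cell genes, 13 rose and 0 fell (median 0.82, camera adjusted p = 0.00201, adjusted p = 0.289 with an estimated correlation), with Lyz2 at 174 ± 12.2 and 220 ± 22.3 FPKM and a log2 fold change of 0.44. The members with the smallest p, C1qb, Cd14, C1qa and Fcer1g, rose by 0.92, 1.05, 0.72 and 1.46 on the log2 scale, all past the threshold. Lyz2 did not pass without wild-type replicate 1 (0.36, adjusted p = 0.0688), nor with limma on quantile normalized FPKM (0.13, adjusted p = 0.348), on rescaled FPKM (0.26, adjusted p = 0.0748) or without trend (0.33, adjusted p = 0.0978). Of 11 B and plasma cell genes, 3 rose and 5 fell, and the list did not pass (camera adjusted p = 0.651). Its members moved in opposite directions. Mzb1 and Jchain rose by 1.64 and 0.95 on the log2 scale and Cd79a changed by -0.74, each past the threshold. The summed FPKM of the list went from 225 in wild type to 315.8 in knockout.

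**Figure D2:**
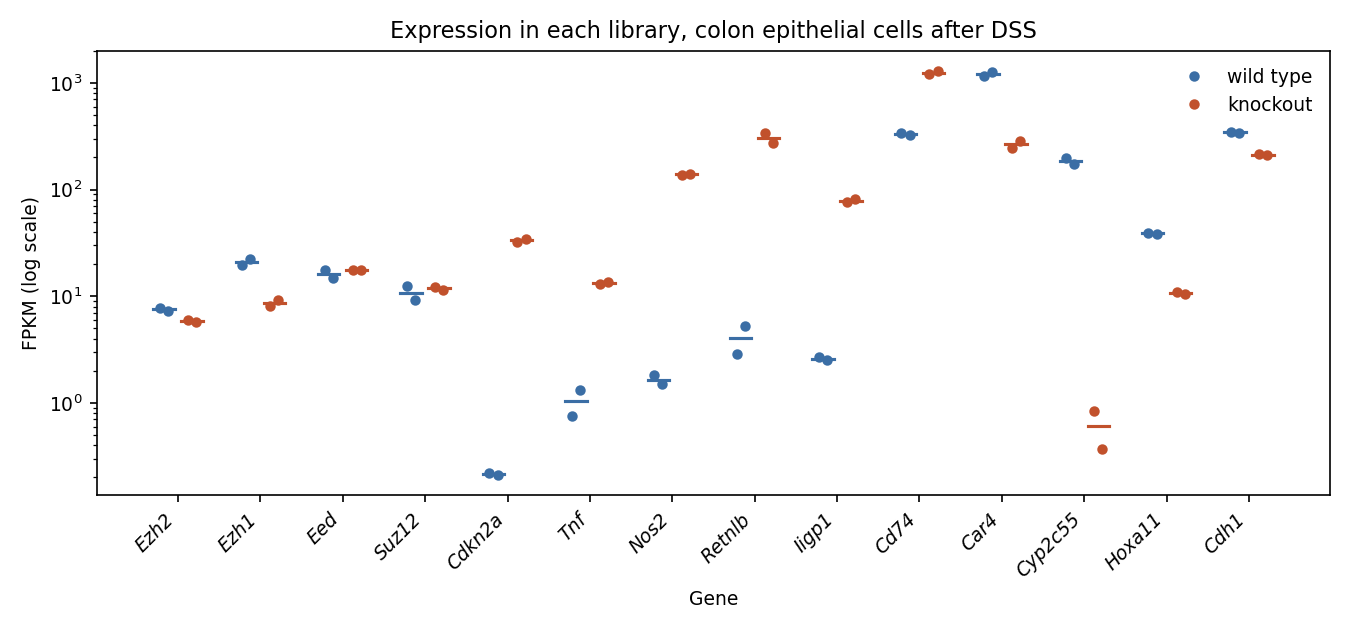
FPKM of 14 genes on a log axis, with a point for each library and a short line at the mean of the 2 libraries of a group, wild type in blue and knockout in orange. Ezh2 goes from a mean of 7.54 to 5.82 FPKM, while Nos2 goes from 1.66 to 139 FPKM and Car4 from 1217 to 267 FPKM.

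Genes of absorptive colonocytes were lower as a group. Of 27 measured, 19 fell and 7 rose, or 19 and 8 adjusted over the list alone (median log2 fold change -1.16, camera adjusted p = 6.13e-05, adjusted p = 0.289 with an estimated correlation). The camera call was also lost on limma fits of FPKM with small pseudocounts or rescaled totals (adjusted p = 0.0551 to 0.0762). Car4, a membrane carbonic anhydrase, fell from 1217 ± 65.1 to 267 ± 27.6 FPKM, and the brush border protease Mep1a fell from 122 ± 11.1 to 15.2 ± 1.54 FPKM. Slc51b, a subunit of the bile acid exporter, rose from 13.3 ± 1.73 to 176 ± 5.11 FPKM. Cdh1, which encodes E-cadherin of adherens junctions, fell from 346 ± 5.18 to 213 ± 3.94 FPKM (log2 fold change -0.60 ± 0.07, adjusted p = 0.000149). Of 24 tight and adherens junction genes, 6 rose and 7 fell (camera adjusted p = 0.67), with Cldn8 at 1.25 and Ocln at -1.15 on the log2 scale, both past the threshold. Regenerative and fetal-like epithelial genes rose. Of 19 measured, 12 rose and 2 fell (median 1.12, camera adjusted p = 1.31e-06, adjusted p = 0.235 with an estimated correlation), with the same counts adjusted over the list alone. Ly6a, also called Sca-1, rose from 238 ± 9.51 to 1999.5 ± 55.5 FPKM and Krt7 from 81.9 ± 1.58 to 323 ± 27.7 FPKM.

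Other epithelial lists did not pass as groups in the main test. Of 22 stem cell and WNT target genes, 3 rose and 10 fell (camera adjusted p = 0.0752, or 0.042 without knockout replicate 2, 0.0403 with no filter and 0.0391 with the replicate block on genes with the same transcripts), among them Lrig1 and Lgr4, which fell by 0.85 and 0.84 on the log2 scale. Of 20 goblet cell genes, 9 rose and 5 fell (adjusted p = 0.0863, or 0.00932 on genes with the same transcripts in all files and 0.0481 with the replicate block added), and Klk1 fell from 935 ± 48.6 to 129 ± 8.72 FPKM. The enteroendocrine list (6 rose and 3 fell of 17, adjusted p = 0.651), the tuft cell list (2 and 3 of 9, adjusted p = 0.346) and the small intestinal and Paneth cell list (3 and 3 of 7, adjusted p = 0.346) did not pass either.

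The measured genes known as Polycomb targets did not rise together. Of 46 fixed developmental and Cdkn2 genes, 22 were measured, and the others were not listed or had too few counts. Of the 22 measured, 2 rose and 13 fell, or 2 and 14 adjusted over the list alone (median log2 fold change -0.68, camera adjusted p = 0.00855, adjusted p = 0.289 with an estimated correlation). Members already expressed in wild type, such as Hoxb13, were not silent there, so their falls do not test loss of silencing. Cdkn2a was the member that rose most. Hoxa11 fell from 38.8 ± 0.83 to 10.7 ± 0.40 FPKM, Hoxd11 from 21.9 ± 0.17 to 7.72 ± 0.20 FPKM and Hoxb13 from 382 ± 15.6 to 169 ± 19.97 FPKM. Markers of stroma fell alongside. Of 20 fibroblast and smooth muscle genes, 17 fell and 2 rose (median -0.88, camera adjusted p = 8.76e-05, adjusted p = 0.507 with an estimated correlation), and Tagln fell from 1028.3 ± 113.6 to 473 ± 96.5 FPKM. All 5 erythroid genes fell (median -2.09, camera adjusted p = 9.65e-05, adjusted p = 0.289 with an estimated correlation). The endothelial and glial list did not pass (1 rose and 5 fell of 18, adjusted p = 0.199, or 0.0442 without knockout replicate 2 and 0.0396 with no filter).

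Proliferation and biosynthesis genes were higher in knockout. Of 40 cell cycle genes, 33 rose and 0 fell, or 35 and 0 adjusted over the list alone (median 0.68, camera adjusted p = 9.38e-09), with Birc5 at 20.4 ± 0.27 and 68.4 ± 1.02 FPKM and Rrm2 at 7.17 ± 0.32 and 22.6 ± 4.46 FPKM. The endoplasmic reticulum stress list had 16 of 19 members higher and 1 lower (median 1.14, camera adjusted p = 9.38e-09), led by Creld2 and Manf with log2 fold changes of 1.98 and 1.77. Cholesterol synthesis genes (16 rose and 1 fell of 20, camera adjusted p = 2.71e-05), hypoxia and glycolysis genes (14 and 2 of 20, adjusted p = 0.00168) and nuclear oxidative phosphorylation genes (25 and 1 of 28, adjusted p = 0.000364) rose as well. Hk2 rose from 51.0 ± 4.38 to 163 ± 3.4 FPKM and Fdps from 85.9 ± 0.35 to 251 ± 18.2 FPKM. With an estimated correlation, each of these 5 lists had an adjusted p = 0.289. Immediate-early and dissociation genes, which tissue handling can induce, had 12 of 21 members higher and 4 lower (camera adjusted p = 0.0275, adjusted p = 0.572 with an estimated correlation), with a summed FPKM of 1157 in wild type and 1126 in knockout. That call was also lost without knockout replicate 2 (adjusted p = 0.063), with a mean FPKM of at least 5 (0.105), on genes with the same transcripts without and with the replicate block (0.063 and 0.0874) and with limma on quantile normalized FPKM (0.182). Neither the apoptosis list (8 rose and 3 fell of 25, adjusted p = 0.117) nor the p53 target list (9 and 3 of 20, adjusted p = 0.234) passed camera's test. Fry called both higher (adjusted p = 0.00911 and 0.0111).

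**Figure D3:**
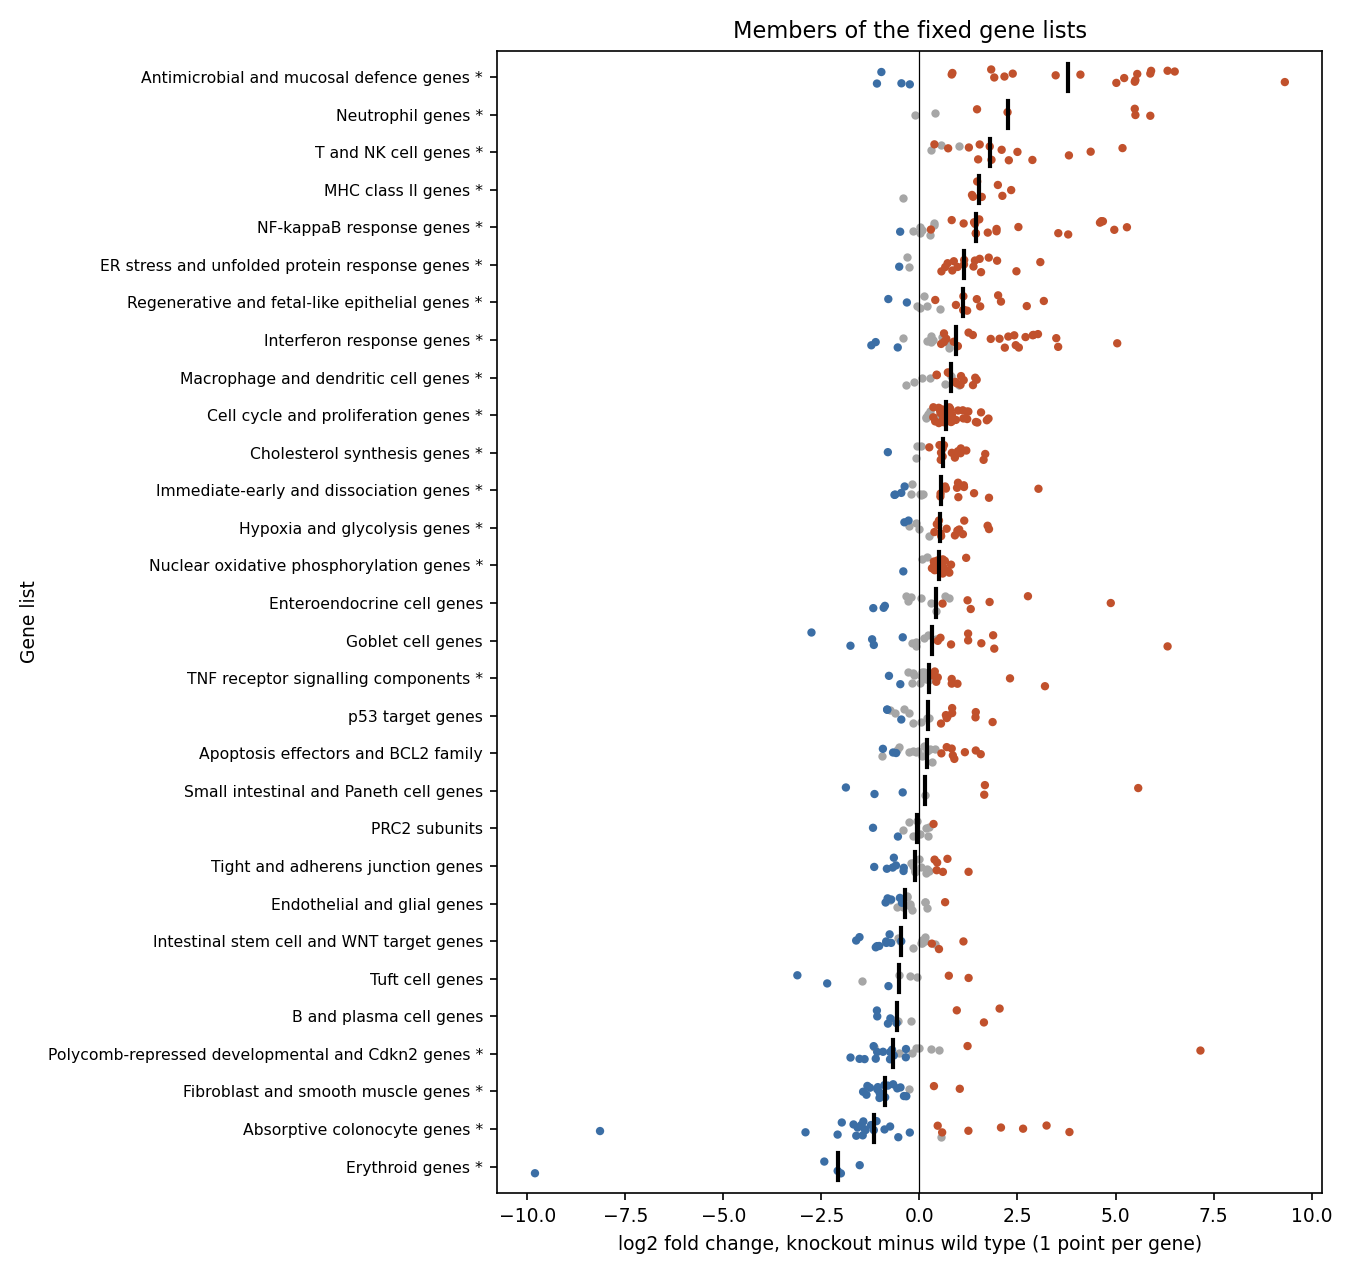
Each point is a measured member of a fixed gene list, with its log2 fold change, knockout minus wild type, on the x axis, and each row is a list. Coloured points pass the adjusted threshold, black bars are medians, and a star marks the 19 lists past camera's test with its preset correlation, of which 0 pass with an estimated correlation. With so few libraries the estimated setting could hardly call any list.

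Camera with its preset correlation called 15 lists higher and 4 lower of 30 tested. With a correlation estimated from these 4 libraries it called 0, and 5 had an unadjusted p under the threshold. That setting relies on the few residual degrees of freedom that 4 libraries leave. An adjusted p under the threshold was therefore hard to reach whatever the correlation, and the 0 calls say little against a list. Rotation tests with fry, which ask whether a list's genes move one way without comparing them with other genes, called 17 higher and 5 lower. Fry added the apoptosis, p53 target and goblet lists as higher and the PRC2 and stem cell lists as lower. It did not call the fibroblast and smooth muscle list (fry adjusted p = 0.05) or the immediate-early list (fry adjusted p = 0.0502). The replicate 1 and replicate 2 files were made with different annotation versions, each holding 1 library per group, so no test can be made within a version. Across all tested genes, the log2 fold changes of the replicate 1 and replicate 2 comparisons had a Pearson r of 0.857, where genes are not independent replicates.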

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

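Library totals without TMM factors, the settings on genes with the same transcripts and the lists without genes that 1 annotation version lists were chosen after seeing the data, and the other alternatives before. With the replicate block, 3858 genes were higher and 3548 lower, and all 5953 genes called without it kept their call and sign. Same-numbered libraries deviated together (r = 0.507 across 9550 genes with the same transcripts), but with 2 pairs and no label on what a number shares, the numbers are not taken as pairs. With the replicate block on genes with the same transcripts the counts were 3692 and 3449. No called gene had an opposite call under any setting of the gene test. Called genes numbered 4610 to 5764 with a library left out, and the lone library is then assumed to vary like the other group. DESeq2 called 2376 higher and 2003 lower. Limma called 2387 higher and 3023 lower on log2(FPKM + 1), 2002 and 3501 on FPKM rescaled to equal totals and 2492 and 2514 on quantile normalized FPKM. Test, input and genes tested differ from edgeR there, and the cause of the difference from 3129 higher was not tested. Requiring a log2 change of at least 1 left 939 higher and 1091 lower, since that threshold is stricter by construction. Ezh2 passed only with limma on FPKM rescaled to equal totals (log2 fold change -0.42, adjusted p 0.0469). Over its alternatives its adjusted p ranged to 0.525 (DESeq2), and without a library its fold change was -0.32 to -0.23. The lists called with an estimated correlation were 0 higher and 0 lower. Estimates were as high as 0.771, for fibroblast and smooth muscle genes. Calls were also lost where the estimate lay below the preset 0.01, as for defence (0.0013), T and NK cell (-0.0362) and neutrophil genes (-0.151). A higher correlation is therefore not why those calls were lost. With an estimated correlation camera uses the few residual degrees of freedom of 4 libraries, and with the preset correlation it does not. For defence genes camera's unadjusted p went from 7.79e-33 to 0.00588 at nearly no correlation. These calls were thus lost to the few degrees of freedom, so their loss says little against the lists.

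Some values not past the threshold changed sign, and the cause was not tested. Rbbp4 (0.01) was -0.0627 with a mean FPKM of at least 5, -0.0907 with library totals, -0.093, -0.0971 and -0.0975 with limma at pseudocounts 1, 0.1 and 0.01, -0.173 rescaled to equal totals, -0.0907 quantile normalized, -0.093 without trend and with robust trend, and -0.16 to 0.165 without a library. Aebp2 (0.17), whose transcript lists differ between annotations, was -0.20, -0.21 and -0.22 with limma at those pseudocounts, -0.29 rescaled, -0.13 quantile normalized and -0.20 without trend and with robust trend. Jarid2 (-0.05) ranged from -0.134 to 0.0194 without a library, the highest without knockout replicate 1. Ly6g, listed in replicate 2 only, ranged from -12.1 to 11.98 without a library, which its absence from the other annotation produces by construction. Rbbp7 lost its call under 6 limma settings (adjusted p 0.0511 to 0.146), and Suz12 passed with the replicate block (adjusted p 0.0319). The enteroendocrine list turned to lower with a mean FPKM of at least 5 (adjusted p 0.699), and the small intestinal and Paneth list with the same transcripts (0.777) and with the replicate block added (0.61).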

Other observations

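The gene families in this and the next paragraph, the clock genes, the on and off genes, and the tests of exchanged libraries, of proliferating cells, of collection time and of the defence genes apart from neutrophil genes were chosen after results had been seen. Every measured immunity-related GTPase and guanylate-binding protein gene rose (18 of 18, median log2 fold change 3.15, camera adjusted p = 4.02e-50, adjusted p = 0.0919 with an estimated correlation). Members such as Iigp1, Igtp and Gbp2 are also in the fixed interferon list, so this family is not separate evidence. Of 20 MHC class I genes, which include near-identical copies, 16 rose and 1 fell, with B2m at 435.5 and 1671 FPKM in wild type and knockout. Of 38 proteasome subunit genes, 36 rose and 0 fell (median 0.93), and of 17 cytosolic aminoacyl-tRNA synthetase genes 14 rose and 0 fell, with Wars at 46.7 and 207.5 FPKM. Cytosolic ribosomal protein genes did not pass as a group (20 rose and 3 fell of 80, median 0.06, less than the shift of -0.103 that library totals give all genes, adjusted p = 0.344). Of 6 small proline-rich protein genes, of which the Sprr2a copies are near-identical and Sprr2a3 is listed by the replicate 2 files only, 5 rose, with Sprr1a at 2.72 and 59.1 FPKM. With an estimated correlation, adjusted p was 0.127, 0.184, 0.268 and 0.127 for the MHC class I, proteasome, synthetase and small proline-rich genes.

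Of 17 cytochrome P450 family 2 genes, 13 fell and 2 rose (median -1.54), and of 10 carboxylesterase genes 6 fell and 2 rose, with Ces2a at 79.1 and 7.04 FPKM. Of 6 UDP-glucuronosyltransferase genes, 4 fell and 1 rose, and of 6 sulfotransferase genes 3 fell and 0 rose, with Sult1a1 at 114.6 and 9.25 FPKM. Of 21 Hox genes, some of which are also in the fixed list of Polycomb targets, 15 fell and 0 rose (median -0.96). Of 17 replication-dependent histone genes, which have close copies and transcripts without poly(A) tails, 12 fell and 0 rose (median -1.97), with H1f2 at 367.5 and 47.3 FPKM, although 33 of 40 cell cycle genes rose. H2bc6 is among those that fell (-1.82), yet its FPKM was 1.89 in wild type and 1.7 in knockout. H2ac10, H2ac22 and H2ac23 did not pass and had wide standard errors of 0.967, 1.2 and 1.33. With an estimated correlation, adjusted p was 0.0919 for the P450 genes, 0.198, 0.184 and 0.127 for carboxylesterase, glucuronosyltransferase and sulfotransferase genes, and 0.127 for both Hox and histone genes.

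Ezh2 counts in the knockout libraries were close to wild type. An exchange of a library between groups is argued against, since chi-square per degree of freedom was at most 2.95 within groups and at least 38.25 between them. More proliferating cells in the knockout, which may mask a lower level per cell, stay open. Of 40 cell cycle genes, 0 had a lower log2 fold change than Ezh2, but both values had been seen when that comparison was chosen, so it does not bear on this explanation. A deletion of some exons that leaves a stable transcript, and Ezh2 from cells outside the epithelium, stay open and were not tested here.

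Clock output genes were lower in the knockout. Of 12, 11 fell (median log2 fold change -1.79, camera adjusted p = 2.63e-15, adjusted p = 0.0919 with an estimated correlation), with Dbp at 94.9 and 8.97 FPKM and Per3 at 16.2 and 2.53 FPKM. Scaling is argued against, since under the scaling nearest 0 the median was -1.61, and so is a trend on GC content or transcript length, after whose removal it was -1.71. Collection at another time of day cannot be told apart from an effect of genotype. The 5 genes of opposite phase had a median of 0.33, where Nfil3 and Cry1 rose, Clock fell and Arntl and Npas2 did not pass, and the labels used here give no collection time.

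Defence, chemokine and interferon genes were higher in the knockout. A trend on GC content or length is argued against by a median of 1.55 for the 83 genes after its removal. Pan-epithelial genes had a median of -0.054 with a standard error of 0.14, which met the rule set beforehand against a larger epithelial share. They were already abundant in wild type, with Krt8 at 3274 FPKM, and the scaling placed the median of all tested genes at -0.002. The test thus had little room for a rise and does not exclude a larger share. Fibroblast and smooth muscle genes and erythroid genes fell, with medians of -0.88 and -2.09. More leukocytes in the preparation may contribute and cannot be told apart from a rise within epithelial cells. The 15 abundant pan-leukocyte genes had a median of 0.75 with a standard error of 0.15, with Lyz2 at 174 and 220 and Cd52 at 44.7 and 91.3 FPKM, which lies between the bounds set beforehand for either outcome, and the 19 defence genes outside the neutrophil list had a median of 2.38 with a standard error of 1.19, too wide to separate from it. An effect of the Ezh2 deletion on these genes is the biological explanation that the design offers and remains a hypothesis.

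Loss of silencing by Ezh2 would be expected to leave more genes on in the knockout alone than in wild type alone. With at most 2 counts in each library of a group and at least 20 in each of the other, 18 genes were on in knockout and 6 in wild type (exact binomial p = 0.0227, two-sided, or 15 against 5 and p = 0.0414 outside the fixed lists), and the former include Cdkn2a, Ghrl, which encodes ghrelin, and Lin28b. The binomial test takes both directions as equally likely. Among called genes with a log2 change of at least 2 in size, 301 were higher and 243 lower, and these p-values do not allow for that lean. The imbalance also depends on the limit. With limits of 2 and 10 counts there were 39 against 20 (exact binomial p = 0.0183) and with 5 and 20 counts 54 against 26 (exact binomial p = 0.00232), but with 0 counts required in the low group there were 5 against 4 (exact binomial p = 1). The genes are not independent of each other, and secondary inflammation may raise genes in the same way, so the count does not single out loss of silencing. In the fixed list of Polycomb targets, 2 of 22 measured members were higher and 13 lower, and of 21 Hox genes 0 were higher and 15 lower. The list and the family share members such as Hoxa11 and Hoxb13, so these counts are not separate results. Falls of members already expressed in wild type do not test loss of silencing.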
